A study of Mus musculus with 2 samples.

How the data were processed

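Single-cell RNA sequencing was performed on lungs of C57Bl6 mice injured with bleomycin, a drug that causes lung fibrosis, on day 1 and given vehicle or navitoclax from day 15 to day 20. Navitoclax (ABT-263) is a small-molecule inhibitor of the anti-apoptotic proteins BCL-2, BCL-XL and BCL-W that is also used to kill senescent cells. Lungs were taken 21 days after injury, and flow-sorted epithelial and stromal cells were combined in equal proportion before capture, so the ratio of epithelial to stromal cells carries no information. Each group had 1 library. How many mice went into a library is not given in the sources used here.

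The deposited values were UMI counts per gene and cell barcode, without normalization, from a Chromium 3′ kit per the labels. The matrices were written by Cell Ranger 4.0.0, per the file headers, and the genome build was mm10, per the submitters' processing notes. Other settings of the alignment and of the cell calling are not given in the sources used here. Each matrix held 27998 genes, and every barcode had at least 500 UMIs. The vehicle library had 8784 barcodes with 97958947 UMIs and a median of 9125 UMIs, and the navitoclax library had 8064 barcodes with 98517048 UMIs and a median of 9920.5 UMIs.

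Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept, which left 7396 vehicle cells (84.2%) and 6445 navitoclax cells (79.9%). Barcodes over the mitochondrial limit made up 13.8% of the vehicle library and 18.1% of the navitoclax library. Doublets were called per library with Scrublet (scanpy 1.11.5, expected rate 6%) and removed, 222 vehicle cells (3.00%) and 217 navitoclax cells (3.37%). A cluster with scores of at least 0.3 for both epithelial and fibroblast markers would also have been removed, but none met this. Free RNA was not subtracted.

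Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, a graph of 15 neighbours that linked cells sharing at least 3 of them, and Leiden clustering (leidenalg 0.10.2) at resolution 1. Epithelial and other clusters were then each clustered again, giving 36 clusters. Cluster names rested on marker lists. A marker counted as detected at 20 CPM, and a name needed at least 3 detected markers, a mean marker level of at least 0.35 of that in the highest cluster, and no other class with more markers among the 10 leading genes. The scoring rule and its thresholds were set after the data were seen. An earlier version of the rule had left a cluster with clear type II markers without a name. The rule left 83 vehicle and 57 navitoclax cells unnamed, and 335 vehicle and 255 navitoclax fibroblasts without a subclass.

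The marker lists, the gene lists, the rule for named genes, the statistics and most alternatives were chosen before the data were examined. Some listed symbols were matched to the older names in the deposited gene table through gene identifiers after list medians had been seen, which brought Cyr61 and Ctgf into the TGFβ list. Of the listed symbols, 3 had no match. Of the 27998 gene identifiers, 27645 were found in GENCODE release M21 (GRCm38), which supplied coordinates.

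With 1 library per group, no test between treatments is possible, and cells were not treated as replicates. Shares of cells were given with exact Clopper-Pearson 95% intervals, and their difference with a Newcombe 95% interval. For genes, UMIs were summed per class and library and expressed as CPM with exact Poisson 95% intervals, and the ratio of CPM had a conditional exact 95% interval. All of these intervals cover counting error only, and neither differences between mice nor between preparations. Classes with at least 100 cells in both libraries were compared, which gave 10 classes, counting the pooled fibroblasts. For each gene list, the median over members with at least 20 UMIs of log2((navitoclax CPM + 5)/(vehicle CPM + 5)) was set against 10000 random lists of the same size matched on mean CPM in 20 bins. A list was called apart from random lists outside their middle 95%. This describes the libraries, not the treatments. Lists were also compared within single type II-like clusters of at least 100 cells per library, chosen for the ATF6 list before and for other lists after the values were seen.

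Genes were named by rule. In type II-like cells, transitional-like cells and pooled fibroblasts, genes with at least 100 UMIs and at least 50 CPM in the higher library were ranked by the interval bound nearest to 1, and the 12 highest and 12 lowest were taken. Unnamed gene models, ribosomal, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes, cell type markers and genes under 10% of their level in the class where they were highest were left out. The pseudoautosomal gene Erdr1 was kept. From each list, up to 3 members with at least 50 UMIs and the greatest absolute log2 ratio were also taken, together with the genes of the drug targets and stress sensors. The text gives examples of the list members so taken, and single values of 3 of the chosen genes are not reported here. To compare shares of cells with a UMI, cells were thinned to 2000 UMIs and shallower cells left out.

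The statistics were tested on simulated data made from these libraries, with 200 genes changed by known folds. Counts were drawn with Poisson error from the UMI sums of each class, which is what the intervals assume. Counts gathered in single cells and differences between mice were therefore not covered by this check. Over 11135 genes of type II-like cells, 95.3% of the intervals included the true ratio. Of the genes changed by a factor of 1.5, 97.2% had an interval that excluded a ratio of 1 in the right direction. The corresponding values were 95.4% and 87.5% over 6391 genes of transitional-like cells, and 95.7% and 96.8% over 11471 genes of fibroblasts.

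Alternatives were a stricter cell filter (at least 1000 genes, at most 10% mitochondrial UMIs) and none, doublets kept, resolutions of 0.5 and 2, clustering each library alone, calling each cell alone, and thinning. For genes and lists they were scaling by TMM (edgeR 4.0.16) or by median of ratios (DESeq2 1.42.0), pseudocounts of 1 and 20 CPM, minimums of 0 and 100 UMIs, equal weights for cells, and equal weights for fibroblast subclasses. Scaling by TMM moved all genes by −0.45 log2 in club-like cells, where the median over all genes was 0.32, and by at most 0.02 in every other compared class. Added after seeing the data were leaving out the cell with the most UMIs of each gene, clustering without dissociation stress genes, leaving out clusters of shallow cells, a limit of 30% mitochondrial UMIs, and leaving out a single transitional-like cell. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3.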

Results

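The series asks how BCL-2 inhibition acts on endoplasmic reticulum (ER) stress, through the ER stress sensor IRE1α, and on lung fibrosis. Lung epithelial and stromal cells of bleomycin-injured mice were profiled after treatment with vehicle or navitoclax, with 1 library per group and therefore no replicate check of any difference. The vehicle library held 97958947 UMIs and the navitoclax library 98517048. After filtering and removal of doublets, 7174 cells of the vehicle library and 6228 of the navitoclax library were assigned to clusters. Intervals throughout are 95% intervals that cover counting error only.

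The question of which cell populations differed was addressed by shares within the epithelial and the fibroblast compartment. The share of alveolar type I-like (AT1-like) cells, the thin gas-exchange cells, was lower in the navitoclax library. It was 1.74% (1.31 to 2.26) there, or 54 of 3107 epithelial cells, and 4.12% (3.48 to 4.85), or 140 of 3395, in the vehicle library, a difference of −2.39 percentage points (−3.21 to −1.58). Most AT1-like cells, 118 vehicle and 49 navitoclax cells, lay in cluster 10. This cluster scored 0.503 for AT1 and 0.552 for transitional markers, with 7 AT1 markers among its 10 leading genes. Alveolar type II-like (AT2-like) cells, the surfactant-producing progenitors of the alveolus, made up 76.2% (74.8 to 77.7) of vehicle and 75.0% (73.4 to 76.5) of navitoclax epithelial cells. Transitional-like cells, an intermediate state between AT2 and AT1 cells that appears after injury, made up 5.68% (4.93 to 6.52) and 6.63% (5.78 to 7.56), a difference of 0.945 points (−0.223 to 2.13) whose direction was not fixed. It turned in 4 of 7 alternatives, with −1.33 points at resolution 2, −1.85 points without dissociation stress genes in the clustering and −1.77 points with up to 30% mitochondrial UMIs, and with each library clustered alone no navitoclax cluster received the name. AT2-like cells had a value in 11 alternatives. Settings in which no cell of either library received the transitional-like name gave no value. Airway-like cells were at 14.0% (12.8 to 15.2) in the vehicle and 16.6% (15.3 to 18.0) in the navitoclax library, a difference of 2.68 points (0.928 to 4.44), mostly from ciliated-like cells with 10.8% and 13.3%. The AT1-like difference depended on the clustering. It was 0.652 points when each library was clustered alone, −0.474 points when dissociation stress genes were left out of the clustering, and −0.415 points with up to 30% mitochondrial UMIs. The class itself shrank in these settings. With each library alone it held 0.646% of vehicle and 1.30% of navitoclax epithelial cells. The shares were 0.632% and 0.158% without dissociation stress genes, and 0.613% and 0.198% with up to 30% mitochondrial UMIs.

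Among fibroblasts, peribronchial-like cells were at 6.27% (5.50 to 7.11) in the vehicle and 8.23% (7.26 to 9.27) in the navitoclax library, a difference of 1.96 points (0.700 to 3.24). The interval of the difference included 0 for the other subclasses. Alveolar-like fibroblasts made up 68.9% and 67.2%, adventitial-like fibroblasts 7.42% and 8.53%, and fibrotic-like fibroblasts, which carry markers of matrix-producing cells of the injured lung, 8.0% (7.14 to 8.94) and 7.49% (6.57 to 8.49). All fibrotic-like cells lay in cluster 23, and the name was close. This cluster scored 0.558 for fibrotic and 0.527 for alveolar fibroblast markers, with 2 fibrotic markers among its 10 leading genes. No cluster passed as inflammatory-like fibroblasts. The difference for fibrotic-like cells was −0.516 points, and it was 1.84 points at resolution 2, so its direction was not fixed by these data. It had a value in 6 alternatives, against 11 for alveolar-like fibroblasts, as settings without a cell of the name gave none. With each library clustered alone, 12.3% of vehicle fibroblasts lay in clusters of this name and no navitoclax cluster received it.

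**Figure D1:**
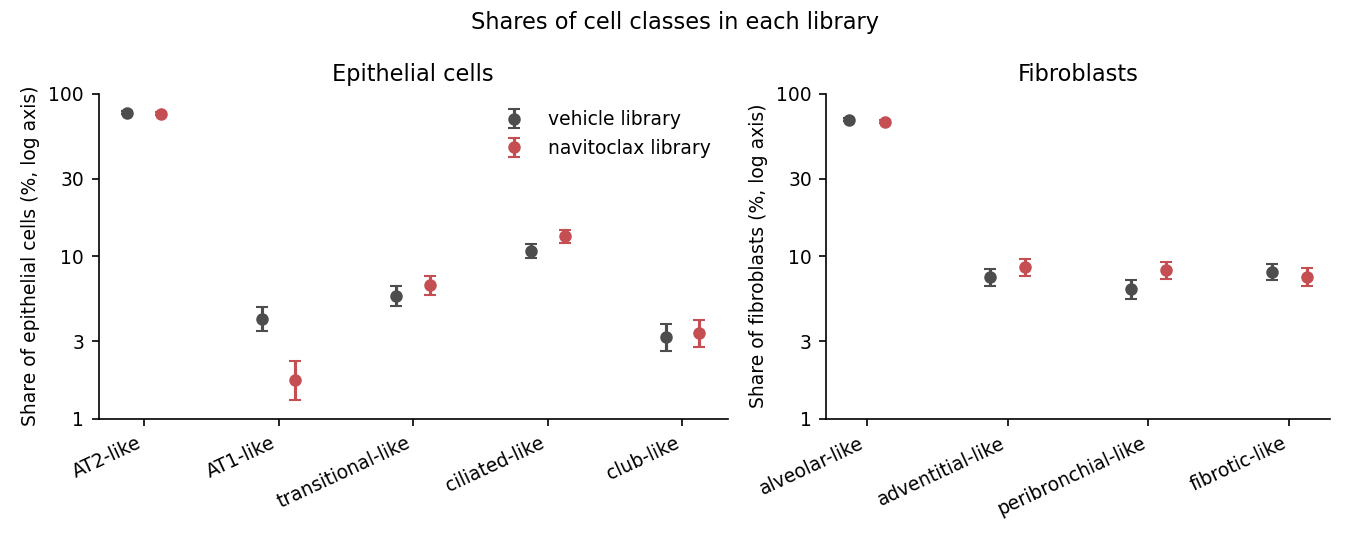
Share of each cell class among epithelial cells (left) and fibroblasts (right), in percent on a log axis, for the vehicle (grey) and the navitoclax library (red); points are shares and bars exact 95% binomial intervals. AT1-like cells sit at 4.12% in the vehicle and 1.74% in the navitoclax library.

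In AT2-like cells (2588 vehicle and 2330 navitoclax cells, 18110.5 and 19776.5 median UMIs), the inducible heat shock genes stood out. Hspa1b was 38.9-fold (35.2 to 43.1) and Hspa1a 34.6-fold (32.1 to 37.3) higher in the navitoclax library, the latter at 14.8 CPM in the vehicle and 511 CPM in the navitoclax library. Both encode the inducible cytosolic Hsp70 chaperone from near-identical copies, so the division of counts between them is uncertain. Their co-chaperone gene Dnajb1 was 1.72-fold (1.62 to 1.83) and Hsp90aa1, the inducible Hsp90, 1.68-fold (1.64 to 1.71) higher. Genes of ER protein folding were higher too, while the stress cytokine gene Gdf15 was lower.

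Other genes higher in the navitoclax AT2-like cells were Retnla (2.05-fold, 1.95 to 2.16), which encodes a secreted resistin-like protein, Rsrp1 (1.94-fold), the potassium channel gene Kcnj2 (1.81-fold), the homeobox gene Irx1 (1.62-fold), the cell cycle regulator Rgcc (1.60-fold), the small GTPase gene Rasl11a (1.55-fold), Phlda1 (1.54-fold) and Ptgs2 (1.45-fold), which encodes cyclooxygenase-2. In the other direction, Erdr1 was 3.39-fold (3.21 to 3.59) lower. This gene lies in the pseudoautosomal region with near-identical sequence on both sex chromosomes, and its counts are uncertain. The linker histone gene Hist1h1c was 2.41-fold lower, Nr1d1, a repressor of the circadian clock, 2.13-fold, and the nuclear long noncoding RNA Neat1 1.74-fold. Zfp36, which encodes an mRNA decay factor, was 1.68-fold lower, the Notch target Hes1 1.60-fold, March7 1.55-fold, Bhlhe40 1.51-fold, the MAP kinase phosphatase gene Dusp1 1.49-fold, Aox3 1.43-fold, Pnrc1 1.39-fold and H3f3b 1.37-fold. Most vehicle AT2-like cells lay in clusters 0, 1, 4 and 7, and most navitoclax AT2-like cells in clusters 3, 1, 5, 0 and 6, so the libraries were unequally mixed within the class. Cluster 15 was led by cell cycle genes. List medians were therefore also taken within the 7 clusters with at least 100 cells of each library.

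Among the ER stress lists, the ATF6 chaperone targets had a median log2 ratio of 0.20 in AT2-like cells, above all 10000 random lists, with 12 of 14 members above 0, and it lay between 0.13 and 0.22 within the 7 clusters. Calr (1.27-fold, 1.24 to 1.30) and Pdia3 (1.26-fold, 1.22 to 1.30), which encode a lectin chaperone and a disulfide isomerase of the ER, were examples. Sdf2l1 was at 1.56-fold (1.37 to 1.77), but its log2 ratio was −0.19 with cells thinned to 2000 UMIs. IRE1-XBP1 targets had a median of 0.12, above all random lists, with 16 of 18 members above 0, and within clusters it was above 0 in 7 of 7 and apart from random lists in 4. Serp1 (1.17-fold) and Tram1 (1.14-fold) were higher, and Dnajb9 was 1.16-fold (1.10 to 1.21) lower. PERK-ATF4-CHOP targets had a median of −0.07, at or below which lay 12 of the 10000 random lists, with 14 of 20 members below 0. Trib3 was 1.30-fold (1.11 to 1.54), Atf3 1.23-fold (1.2 to 1.27) and Nupr1 1.18-fold (1.17 to 1.2) lower. This last call was lost at resolution 2 (−0.04) and with a minimum of 100 UMIs (−0.05). Within clusters the PERK-ATF4-CHOP median ran from −0.11 to 0.15, below the middle 95% of random lists in 1 of 7 and above it in 1, so the value over all AT2-like cells was not seen within most clusters.

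Of the p53 targets, 17 of 20 were below 0 in AT2-like cells, with a median of −0.06. This call was lost in 6 of 18 alternatives, and within clusters the median was above 0 in 4 of 7 and apart from random lists in 0. Btg2 was 1.37-fold (1.34 to 1.41), Cdkn1a, which encodes the cell cycle inhibitor p21, 1.36-fold (1.31 to 1.41) and Phlda3 1.36-fold (1.26 to 1.47) lower. The senescence list was not apart from random lists (median 0.02, percentile 82.1). In it, Gdf15 was 2.57-fold (2.34 to 2.82) lower, against 1.71-fold (1.49 to 1.96) higher in fibroblasts, and Cxcl1 1.55-fold (1.28 to 1.87) higher. NRF2 antioxidant genes had a median of −0.10 with 13 of 17 below 0, among them Srxn1 (1.36-fold lower). This call was lost in 2 of 18 alternatives. NFκB and cytokine genes had a median of −0.07, but the call was lost in 12 of 18 alternatives, with values up to −0.00055. Within clusters either list lay below the middle 95% of random lists in 1 of 7. Ccl20 went from 320 to 10 UMIs between the vehicle and the navitoclax library, and a single vehicle cell held 176 of the 320. Cell cycle genes had a median of 0.12 with 21 of 22 above 0, and within the 7 clusters the median was apart from random lists in 0. Cluster 15, with 15 vehicle and 26 navitoclax cells, held 35.9% and 45.0% of the UMIs of this list. Top2a was 1.85-fold (1.5 to 2.29) and Mki67 1.52-fold (1.28 to 1.82) higher. All 7 MHC class II genes were above 0 (median 0.15), as in H2-Ab1 (1.2-fold, 1.19 to 1.22), and within clusters the median was above 0 in 7 of 7 and apart from random lists in 2. Interferon genes had a median of 0.07. The interferon call was lost in 4 of 18 alternatives, and within clusters its median was below 0 in 5 of 7, below the middle 95% of random lists in 2 and above it in 0.

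Collagen and matrix genes had a median of 0.08 and contractile genes of 0.11 in AT2-like cells, although many of these are genes of stromal cells. Col1a1 was at 205 UMIs in the vehicle and 328 in the navitoclax AT2-like cells. A UMI of it was seen in 0.971% and 1.25% of thinned AT2-like cells. Within clusters both medians were above 0 in 7 of 7, and above the middle 95% of random lists in 6 for matrix and 4 for contractile genes. The median of contractile genes was −0.02 at resolution 0.5. Cholesterol synthesis had a median of 0.05 at percentile 98.3, a call lost in 5 of 18 alternatives, although within clusters the median lay above the middle 95% of random lists in 6 of 7 and below it in 1. Lists that were not apart from random lists in AT2-like cells were the TGFβ response (0.02, with Id1 1.59-fold lower and Bambi 1.39-fold higher), anti-apoptotic (0.00) and pro-apoptotic (0.03) BCL-2 family genes, substrates of IRE1-dependent decay (0.06), fatty acid synthesis (−0.00), niche signals (0.00), Wnt response (−0.02), glycolysis and hypoxia (−0.01), oxidative phosphorylation (0.03), and proteasome and ER-associated degradation (0.01).

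In transitional-like cells (193 vehicle and 206 navitoclax cells, all in cluster 8, whose leading genes held as many AT2 as transitional markers), genes of the integrated stress response and of p53 were lower in the navitoclax library. PERK-ATF4-CHOP targets had a median log2 ratio of −0.33, below all 10000 random lists, with 17 of 20 members below 0. Trib3 was 2.52-fold (1.55 to 4.20), Ddit3, which encodes CHOP, 1.63-fold (1.27 to 2.09) and Atf3 1.42-fold (1.31 to 1.53) lower. Of the p53 targets, 14 of 19 were below 0 (median −0.25), with Cdkn1a 1.72-fold (1.60 to 1.85), Phlda3 1.53-fold and Trp53inp1 1.53-fold lower. The p53 median was 0.02 when each cell was called alone.

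The ATF6 chaperone list had a median of −0.27 in transitional-like cells, and this rested on 1 cell. A single vehicle cell with 21843 UMIs held 1190 of the 6445 UMIs of this list in the vehicle class, and the next highest cell held 285. Without this cell the median was 0.05 for the ATF6 list and the log2 ratio of Hspa5 was 0.03, against −0.59 with it. The same cell held 136 of the 578 vehicle UMIs of Herpud1, which was 1.92-fold (1.68 to 2.20) lower with it. PERK-ATF4-CHOP targets kept a median of −0.20 without it, while the log2 ratio went from −0.90 to −0.63 for Trib3, from −0.62 to −0.38 for Ddit3 and from −0.49 to −0.48 for Atf3. Pro-apoptotic BCL-2 family genes had a median of −0.25 over 8 members, with Bbc3 (1.75-fold, 1.34 to 2.30), Bik (1.47-fold) and Bax (1.26-fold) lower. NRF2 genes had a median of −0.15 and were at 0.05 when each cell was called alone. Proteasome and ER-associated degradation genes had a median of −0.10, a call lost in 4 of 11 alternatives, with values up to −0.02.

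Gdf15 was 2.75-fold (2.36 to 3.22) lower in navitoclax transitional-like cells, and a UMI of it was seen in 16.2% (11.3 to 22.2) of vehicle and 8.29% (4.91 to 12.9) of navitoclax cells after thinning, which left out 2 and 1 cells. Without thinning these shares were 33.7% and 23.8%. In ciliated-like cells they were 0% and 1.21% after thinning, with median depths of 10042.5 and 12494.5 UMIs against 15727 and 18079 in transitional-like cells. Erdr1 was 3.51-fold, Hist1h1c 2.71-fold, the protease inhibitor gene Spink5 2.59-fold, the oxidative stress gene Osgin1 2.39-fold, Hes1 1.88-fold, Nr1d1 1.81-fold, the cytokine signalling inhibitor Cish 1.78-fold, the cyclin gene Ccnd2 1.74-fold and Gclm, for glutathione synthesis, 1.68-fold lower. A single vehicle cell held 93 of 319 vehicle UMIs of Gclm, which was 1.27-fold lower without the top cells.

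Higher in navitoclax transitional-like cells were Hspa1a (10.5-fold, 9.13 to 12.1), Hspa1b (7.69-fold, 6.58 to 9.03), Emp1 (2.48-fold, 2.03 to 3.06), which encodes an epithelial membrane protein, Rsrp1 (2.03-fold), Dnajb1 (1.84-fold), the matricellular genes Cyr61 (1.77-fold) and Thbs1 (1.48-fold), the isoprenoid synthesis gene Idi1 (1.61-fold), Phlda1 (1.53-fold), Irx1 (1.45-fold) and Tmsb4x (1.32-fold), which encodes an actin-binding peptide. Crct1 had 0 UMIs in the vehicle and 592 in the navitoclax class, at least 162-fold higher against a floor of 3 counts, but 589 of the 592 were in 1 cell. Cholesterol synthesis genes had a median of 0.23, above all random lists, with 16 of 19 above 0, including Insig1 (1.48-fold) and Msmo1 (1.36-fold). Collagen and matrix genes had a median of 0.26 over 15 members, with Col6a1 at 1.36-fold (1.15 to 1.61), and contractile genes of 0.24 over 9, with Tpm2 at 1.97-fold (1.45 to 2.70). Many of these are genes of stromal cells, and Col6a1 was at 70.7 and 96.1 CPM against 683 and 819 CPM in fibroblasts, where it was 1.2-fold higher as well.

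Lists not apart from random lists in transitional-like cells were IRE1-XBP1 targets (−0.04, 12 of 18 below 0), senescence (0.05), TGFβ response (−0.02), NFκB and cytokine genes (0.03), interferon (0.02), MHC class II (0.14), anti-apoptotic BCL-2 family (0.06), substrates of IRE1-dependent decay (0.11), fatty acid synthesis (0.03), niche signals (−0.02), Wnt response (0.02), glycolysis and hypoxia (−0.08), oxidative phosphorylation (0.07), and cell cycle (−0.01). Within them, the neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 were at 12 and 7 UMIs in the vehicle and at 173 and 99 in the navitoclax class. Cxcl1 was 11.9-fold (6.62 to 23.4) higher, and 6.87-fold higher without the top cell of each library. These counts came from few cells, 9 vehicle and 14 navitoclax cells for Cxcl1 and 4 and 9 for Cxcl2. A single navitoclax cell held 98 of the 173 Cxcl1 UMIs.

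In fibroblasts (3573 vehicle and 2978 navitoclax cells), heat shock, matrix, contractile, interferon and cholesterol synthesis genes were higher in the navitoclax library. Hspa1b was 14.4-fold (13.3 to 15.5), Hspa1a 9.62-fold (9.20 to 10.1), Dnajb1 3.28-fold (3.11 to 3.46), the small heat shock protein gene Hspb1 1.95-fold (1.91 to 1.98), the constitutive Hsp70 gene Hspa8 1.83-fold (1.79 to 1.87) and Hsp90aa1 1.54-fold higher. The glucocorticoid-induced kinase gene Sgk1 was 2.22-fold (2.05 to 2.41), Rsrp1 1.82-fold, the interferon-induced Ifi27l2a 1.65-fold, Stbd1 1.63-fold, the metalloproteinase inhibitor Timp1 1.62-fold and Amotl2, which encodes an angiomotin family protein, 1.60-fold higher. Cluster 18 held 928 vehicle and 475 navitoclax alveolar-like fibroblasts and cluster 19 held 413 and 532, cluster 26 was led by Cdkn1a, Ccl2 and Phlda3, and cluster 33 by interferon genes. Unlike in AT2-like cells, lists were not compared within single fibroblast clusters, so the unequal mix of clusters was not checked there.

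Lower in navitoclax fibroblasts were Erdr1 (2.34-fold), Hes1 (2.13-fold, 2.06 to 2.20), Txnip (1.81-fold), which encodes a thioredoxin inhibitor, the kinase gene Pim1 (1.81-fold), the stress gene Gadd45b (1.73-fold), Id1 (1.57-fold), a target of BMP signalling, Tnfaip2 (1.56-fold), H3f3b (1.56-fold), Chrdl1 (1.55-fold), a BMP antagonist, Hist1h1c (1.54-fold) and Rgs2 (1.53-fold), a regulator of G protein signalling. Spp1, which encodes osteopontin, was 18.0-fold (16.5 to 19.7) lower, but a single vehicle cell held 9167 of the 9968 vehicle UMIs, and without the top cell of each library the ratio was 1.98-fold.

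Collagen and matrix genes had a median log2 ratio of 0.26 in fibroblasts, above all 10000 random lists, with 24 of 28 members above 0. Vcan (1.72-fold, 1.57 to 1.89) and Lum (1.42-fold, 1.36 to 1.48), which encode proteoglycans, were examples. Contractile genes had a median of 0.19 with 15 of 16 above 0, with Tagln at 1.70-fold (1.65 to 1.76) and Acta2, smooth muscle actin, at 1.67-fold (1.58 to 1.75). The senescence list had a median of 0.30, above all random lists, with 15 of 18 above 0. In it, Ccnd1, which encodes a cyclin, was 1.70-fold (1.5 to 1.94) higher. Several of its members are matrix remodelling genes, such as Timp1, which is also in the matrix list. The TGFβ response list was not apart from random lists (−0.02, 9 of 20 above 0).

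IRE1-XBP1 targets had a median of 0.19 in fibroblasts, above all random lists, with 14 of 18 above 0, including Edem1 (1.31-fold, 1.18 to 1.46), Serp1 (1.22-fold) and Ostc (1.21-fold). ATF6 chaperone targets had a median of 0.15 with 12 of 14 above 0, led by Hspa5, which encodes the ER chaperone BiP (1.34-fold, 1.32 to 1.38). PERK-ATF4-CHOP targets had a median of 0.09 at percentile 99.1, with 11 of 18 above 0, and this call was lost in 6 alternatives. Cholesterol synthesis had a median of 0.25 with 18 of 19 above 0, such as Idi1 (1.48-fold), and fatty acid synthesis of 0.08. Interferon genes had a median of 0.23 with 22 of 23 above 0, including Irf7 (1.85-fold, 1.57 to 2.20) and Isg15 (1.57-fold). Medians were 0.21 for MHC class II, 0.10 for NFκB and cytokine genes and 0.10 for NRF2 genes. The MHC class II and NFκB medians were both −0.01 with cells thinned to 2000 UMIs. The calls were also lost in 2 of 19 alternatives for MHC class II, in 6 for NFκB and in 5 for NRF2 genes. The MHC class II gene Cd74 was at 33.6 and 42.8 CPM in fibroblasts against 4108 and 4575 CPM in AT2-like cells, so free RNA of AT2-like cells remains open for this list.

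Not apart from random lists in fibroblasts were p53 targets (0.04), anti-apoptotic (0.02) and pro-apoptotic (0.04) BCL-2 family genes, substrates of IRE1-dependent decay (0.05), niche signals (−0.04), Wnt response (−0.03), glycolysis and hypoxia (0.02), oxidative phosphorylation (0.01), proteasome and ER-associated degradation (0.00), and cell cycle (0.04). The pro-apoptotic list was at −0.26, below random lists, with cells thinned to 2000 UMIs. Within the Wnt list, Lgr5 was 1.95-fold (1.63 to 2.33) higher and Dkk2 1.71-fold (1.37 to 2.15) lower.

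**Figure D2:**
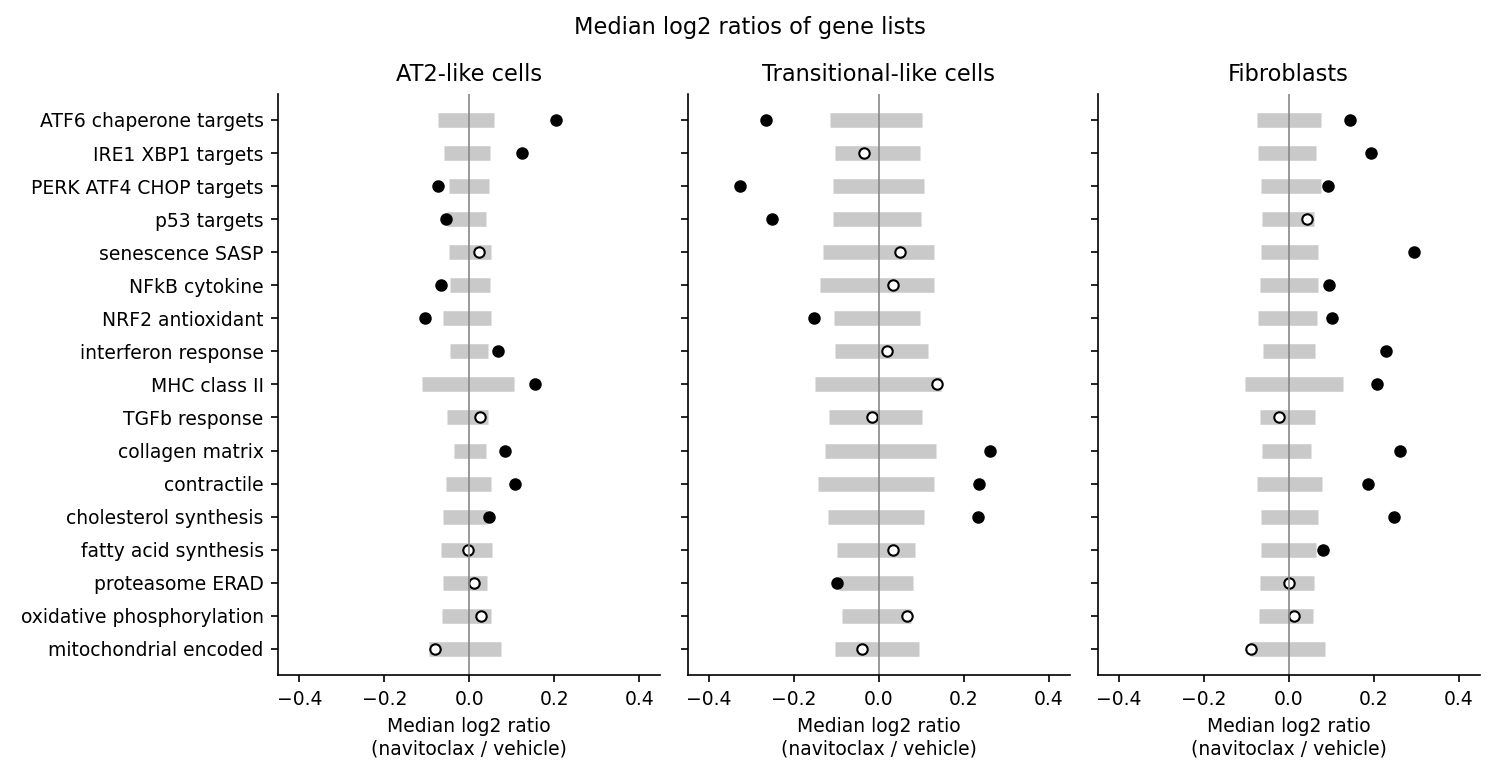
Median log2 ratio (navitoclax over vehicle, x axis) of 17 gene lists in AT2-like cells, transitional-like cells and fibroblasts; grey bars span the middle 95% of 10000 random lists, and filled points lie outside it. ATF6 targets lie at 0.20, −0.27 and 0.15, where the −0.27 became 0.05 without 1 vehicle cell.

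For 7 heat shock genes, Hspa1a, Hspa1b, Hspa8, Hsph1 and Dnajb1 of the dissociation stress list, and Hspb1 and Hsp90aa1, chosen after their values were seen, the interval of the ratio lay above 1 in all 10 compared classes. The lowest of these 70 ratios was 1.04 for Hspa8 in transitional-like cells. Hspa1a ranged from 4.34-fold (3.88 to 4.85) in adventitial-like fibroblasts to 48.0-fold (35.2 to 67.2) in club-like cells, where all genes together were shifted by a median log2 ratio of 0.32. After thinning, a UMI of Hspa1a was seen in 2.76% (2.16 to 3.47) of vehicle and 46.8% (44.8 to 48.9) of navitoclax AT2-like cells, with 13 and 10 shallower cells left out. In ciliated-like cells, Hspa1a was at 13.8 CPM and 88.3 CPM and Dnajb1 at 82.5 CPM and 299 CPM in the vehicle and navitoclax library. The other genes of the dissociation stress list, mostly immediate-early genes, had median log2 ratios over 16 genes of −0.14 in AT2-like cells, −0.10 in transitional-like cells and −0.12 in fibroblasts, below the middle 95% of random lists. In ciliated-like cells their median was 0.19, above all random lists, with 12 of 15 genes above 0. The whole dissociation stress list, heat shock genes included, had medians of 0.01, 0.06 and 0.02 in AT2-like cells, transitional-like cells and fibroblasts.

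**Figure D3:**
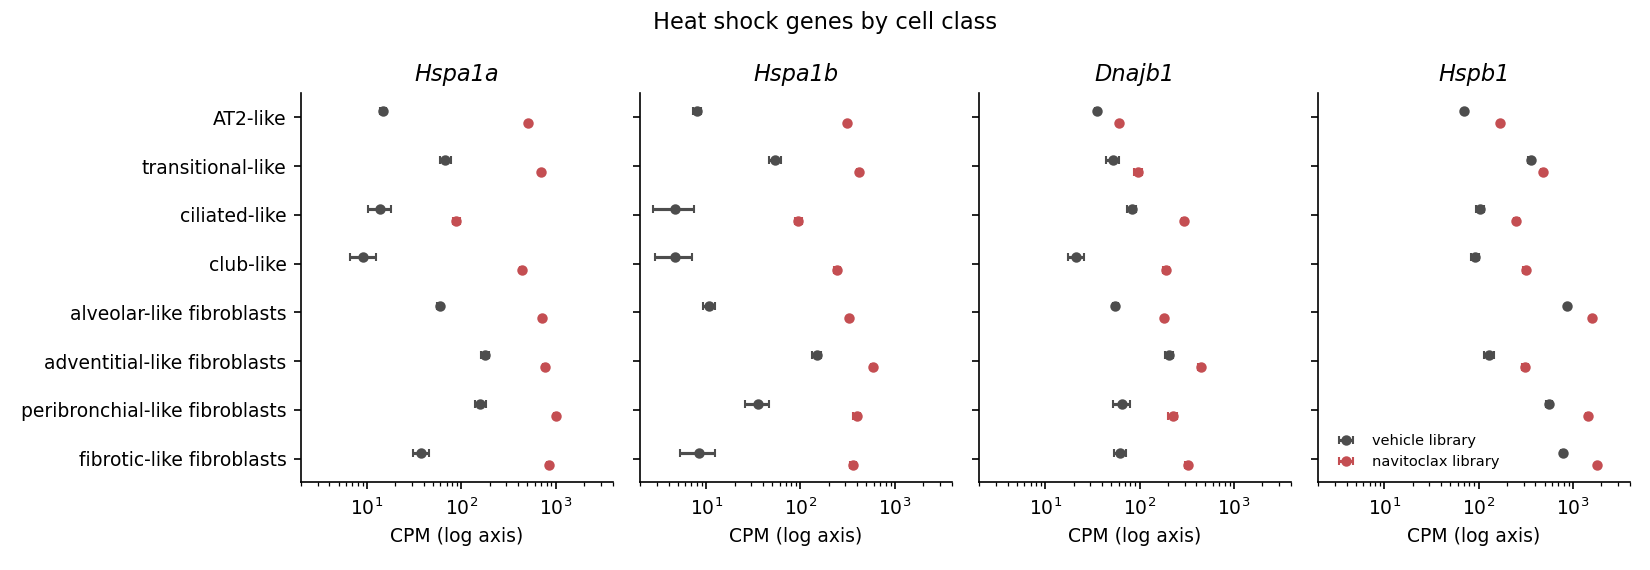
CPM of Hspa1a, Hspa1b, Dnajb1 and Hspb1 (x axis, log scale) by cell class in the vehicle (grey) and navitoclax library (red), with exact 95% Poisson intervals. The navitoclax value lies to the right in each class shown, as in AT2-like cells with 14.8 and 511 CPM of Hspa1a.

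The proteins that navitoclax binds are encoded by Bcl2 (chromosome 1, 106538178 to 106714274, GRCm38), Bcl2l1 (chromosome 2, 152780668 to 152831728) and Bcl2l2 (chromosome 14, 54883377 to 54888234). Bcl2 was at 49.7 CPM (47.1 to 52.4) in vehicle and 47.9 CPM (45.2 to 50.7) in navitoclax fibroblasts, and at 2.95 and 3.40 CPM in AT2-like cells. Its ratio had an interval that included 1 in AT2-like cells, transitional-like cells and fibroblasts. A UMI of Bcl2 was seen in 9.08% and 9.30% of thinned fibroblasts, with 323 and 290 cells left out, in 27.6% and 29.5% without thinning, and in 1.91% and 1.46% of thinned ciliated-like cells. The median depth was 7216 and 7764 UMIs in fibroblasts. Bcl2l1 was at 42.8 CPM in AT2-like cells of both libraries. Bcl2l2 was higher in the navitoclax library, by 1.34-fold (1.22 to 1.49) in AT2-like cells and 1.28-fold (1.11 to 1.49) in fibroblasts, and Mcl1, an anti-apoptotic gene whose protein navitoclax does not target, by 1.09-fold (1.06 to 1.12) in AT2-like cells. In the other direction, the anti-apoptotic genes Bcl2a1b and Bcl2a1a were 1.49-fold (1.37 to 1.62) and 1.28-fold (1.06 to 1.55) lower in AT2-like cells, and as near-identical copies their counts are uncertain.

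Ern1 (chromosome 11, 106394650 to 106487852), which encodes IRE1α, was at 13.0 CPM (12 to 14.1) in vehicle and 14.3 CPM (13.2 to 15.4) in navitoclax AT2-like cells, a difference not detectable at this depth. Total mRNA of its target Xbp1 (chromosome 11, 5520659 to 5525893) was 1.08-fold (1.04 to 1.12) lower in AT2-like cells, 1.26-fold (1.07 to 1.47) lower in transitional-like cells and 1.06-fold (1.02 to 1.10) lower in fibroblasts of the navitoclax library. Counts at the 3′ end do not show the splicing of Xbp1 by IRE1α. Hspa5 (chromosome 2, 34771970 to 34777547) was 1.15-fold (1.13 to 1.18) higher in AT2-like cells. Ddit3 was 1.01-fold (0.913 to 1.12) in AT2-like cells and 1.11-fold (1.04 to 1.18) in fibroblasts, and the ratio of Atf4 had an interval that included 1 in AT2-like cells, transitional-like cells and fibroblasts. Cdkn1a (chromosome 17, 29090976 to 29100727) was lower in AT2-like and transitional-like cells and 1.18-fold (1.15 to 1.22) higher in fibroblasts. Cdkn2a, which encodes the senescence marker p16, was near the detection limit, with 4 and 3 UMIs in AT2-like cells, 0 and 0 in transitional-like cells and 10 and 6 in fibroblasts.

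**Figure D4:**
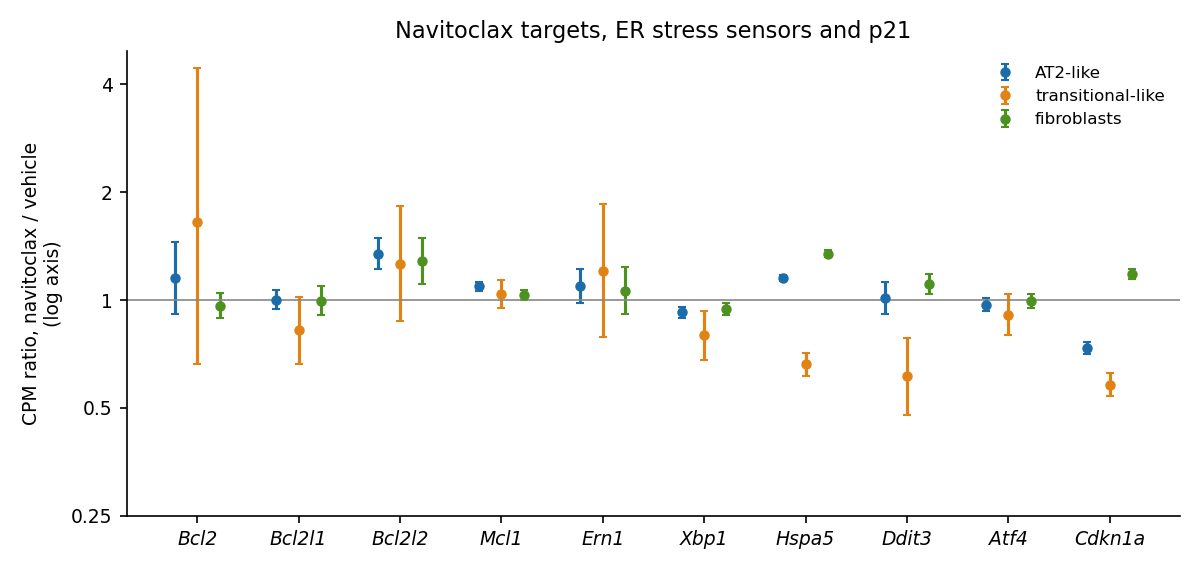
Ratio of CPM, navitoclax over vehicle (y axis, log scale), of the navitoclax target genes, ER stress genes and Cdkn1a in AT2-like cells (blue), transitional-like cells (orange) and fibroblasts (green), with conditional exact 95% intervals. Cdkn1a lies at 0.735, 0.580 and 1.18, and the low transitional-like value of Hspa5 (0.662) rests on 1 vehicle cell.

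Measures of RNA quality and of other cell types were compared over all kept cells. The median share of mitochondrial UMIs in kept cells was 4.61% in both libraries, and mitochondrially encoded genes had medians of −0.08, −0.04 and −0.09 in AT2-like cells, transitional-like cells and fibroblasts, within the middle 95% of random lists. Endothelial markers were at 41.3 CPM in the vehicle and 38.4 CPM in the navitoclax library, pericyte markers at 94.5 and 89.6, lymphocyte markers at 18.7 and 18.3, neutrophil markers at 1.10 and 1.43, erythroid and platelet markers at 4.02 and 4.90, Schwann cell markers at 6.89 and 7.13, mesothelial markers at 118 and 79.6, and proliferation markers at 16.1 and 23.6. Macrophage markers were at 20021 and 23281 CPM, but this list holds Lyz2, which AT2 cells express. Clusters named as endothelial-like held 9 cells in each library and as macrophage-like 8, the latter also led by the plasma cell genes Jchain and Mzb1. Sftpc, the surfactant gene of AT2 cells, gave a UMI in 96.1% and 97.3% of thinned fibroblasts, so free RNA of abundant epithelial genes was present in both libraries.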

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

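The tests of equal weights and thinning, of the cell filter and of barcodes with many mitochondrial UMIs were chosen after the results were seen, and the tests of the ATF6 list within clusters and of AT1 markers before. Several lists lay on opposite sides of random lists in different cell classes, and the difference between classes was not tested, since each class has 1 library per group. ATF6 chaperone targets had medians of 0.20 in AT2-like cells, −0.27 in transitional-like cells and 0.15 in fibroblasts, where the −0.27 rests on a single vehicle cell. PERK-ATF4-CHOP targets had medians of −0.074, −0.33 and 0.093. The −0.33 became −0.20 without that cell, the −0.074 was not seen within most AT2-like clusters, where 2 of 7 medians were above 0 and 1 of 7 lay below the middle 95% of random lists, and the 0.093 lost its call in 6 of 19 alternatives. NRF2 genes had medians of −0.10, −0.15 and 0.10, and the calls were lost in 2 of 18 alternatives in AT2-like cells and 5 of 19 in fibroblasts, and the transitional-like value reversed in 1 of 11. NFκB and cytokine genes had medians of −0.066 in AT2-like cells, where the call was lost in 12 of 18 alternatives, and 0.095 in fibroblasts, where it was lost in 6 and reversed in 1 of 19. Barcodes over 15% mitochondrial UMIs, which entered no comparison, made up 18.1% of the navitoclax library.

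The higher ATF6 chaperone list in navitoclax AT2-like cells was weighed against 3 technical explanations. Within single clusters the median over 7 clusters was 0.18, and all 7 lay between 0.13 and 0.22, which argues against a different mix of clusters as the whole cause. The median was 0.20 with cells weighted equally and 0.13 with cells thinned to 2000 UMIs, at percentiles 100 and 99.8, which argues against a few deep cells and against depth. Any other difference between the preparations stays open beside the drug, because treatment and library are the same split.

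The lower AT1-like share in the navitoclax library may have a technical source. Without any cell filter the difference was −2.69 points (−3.56 to −1.83), which argues against the filter as the whole cause. It shrank to −0.415 points with a limit of 30% mitochondrial UMIs, where the class held 0.613% of vehicle and 0.198% of navitoclax epithelial cells. It reversed to 0.652 points with each library clustered alone, where the class held 0.646% and 1.30%. In both settings fewer cells received the name than in the chosen clustering. Of 10 AT1 markers, 6 were at least 10 times higher in AT1-like than in AT2-like cells. Over all epithelial cells, regardless of clusters, these 6 were all lower in the navitoclax library, each with an interval below 1. They ran from 1.28-fold (1.24 to 1.31) for Hopx to 3.72-fold (3.18 to 4.37) for Spock2. Ager, Aqp5, Emp2 and Cldn18, which AT2-like cells also express, were at log2 ratios of −0.04, −0.07, −0.12 and 0.01. The median log2 ratio of the 6 was −0.53, between the bounds set in advance. That test therefore could not tell the naming of clusters apart from a true difference as the source of the lower share. The 6 markers were chosen by their levels in the named classes, but their counts were summed over all epithelial cells. Where the AT1-like class was bounded therefore does not change those counts, while the source of the lower share stays undecided. The navitoclax library also had 4.32 points (3.21 to 5.43) more barcodes over 15% mitochondrial UMIs, and a loss of these fragile cells in digestion, sorting or capture cannot be told apart from fewer AT1 cells in the lung, so an effect of the drug was not tested.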

How the results depend on the processing

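The settings without dissociation stress genes, without clusters of shallow cells, with a limit of 30% mitochondrial UMIs, without the top cell of each gene and without a single cell were chosen after the data were seen, the others before. No paired analysis was possible because each group has 1 library. Of 286 gene results, 259 kept their sign in every alternative. Of 75 list results, 40 kept their call, which includes lists that stayed within random lists. In every alternative run, IRE1-XBP1 and ATF6 targets stayed apart from random lists in AT2-like cells. The same held for PERK targets in transitional-like cells and for the IRE1-XBP1, ATF6, senescence and matrix lists in fibroblasts. PERK targets in transitional-like cells had only 11 alternatives, against 18 for lists in AT2-like cells and 19 in fibroblasts. Senescence and TGFβ lists in AT2-like cells and IRE1-XBP1 targets in transitional-like cells stayed not apart from random lists. The cause was not tested where a value moved, except where a single cell was left out. Few cells or few UMIs widen the counting intervals, and the spread between mice and preparations was not measured.

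Shares had a value in 11 alternatives for AT2-like cells, 7 for transitional-like cells and 6 for fibrotic-like fibroblasts. Settings without a cell of the name gave none. Differences in shares, in percentage points, moved as follows. AT2-like cells were at 1.04 without a cell filter. AT1-like cells were at −1.57 with the stricter filter, 0.652 with each library clustered alone, −0.474 without dissociation stress genes and −0.415 with 30% mitochondrial UMIs. Transitional-like cells were at −1.33 at resolution 2, −3.91 with each library alone, where no navitoclax cluster received the name, −1.85 without dissociation stress genes and −1.77 with 30% mitochondrial UMIs. Fibrotic-like fibroblasts were at 1.84 at resolution 2, −12.3 with each library alone, again with no navitoclax cluster of the name, and 1.07 with each cell called alone. Inflammatory-like fibroblasts, absent from the chosen clustering, were at 0.0258 with the stricter filter, −0.117 at resolution 2, 1.34 with each cell called alone and 1.27 after thinning. Alveolar-like fibroblasts were at −4.22 at resolution 2, 11.3 with each library alone, −6.90 with each cell called alone and −4.51 after thinning. Adventitial-like fibroblasts were at 3.75 with each library alone, and peribronchial-like fibroblasts at 3.33 with each cell called alone, against 1.96 in the chosen clustering.

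List medians moved as follows. In AT2-like cells, PERK targets were at −0.044 at resolution 2 and −0.051 with at least 100 UMIs, and contractile genes at −0.015 at resolution 0.5. In transitional-like cells, ATF6 targets were at −0.084 with cells weighted equally, −0.022 without the top cell of each gene and 0.045 without the cell richest in the list. With each cell called alone, p53 targets were at 0.023, senescence genes at −0.18 and NRF2 genes at 0.046, and TGFβ genes were at −0.14 with at least 100 UMIs. In fibroblasts, PERK targets were at 0.051 with each library alone, 0.065 with each cell called alone, 0.085 after thinning, 0.043 with a pseudocount of 20 CPM, 0.079 with cells weighted equally and 0.057 with subclasses weighted equally. MHC class II genes were at −0.0074 and NFκB genes at −0.0081 after thinning. In the same direction, calls were lost in AT2-like cells in 12 of 18 alternatives for NFκB genes, 6 for p53 targets, 5 for cholesterol synthesis, 4 for interferon genes, 2 each for NRF2 and matrix genes and 1 for cell cycle genes. In transitional-like cells they were lost in 4 of 11 for proteasome and ER-associated degradation genes, 2 each for pro-apoptotic BCL-2 family and contractile genes and 1 for matrix genes, and in fibroblasts in 6 of 19 for NFκB, 5 for NRF2 and 2 for MHC class II genes. Other lists gained a call. In AT2-like cells these were oxidative phosphorylation (up to 0.061) and mitochondrially encoded genes in 2 of 18 alternatives each, and substrates of IRE1-dependent decay (0.075), niche signals (0.10) and dissociation stress genes (0.058) in 1. In transitional-like cells they were NFκB genes in 2 of 11 (up to 0.46), and interferon (0.26), fatty acid synthesis (0.15), oxidative phosphorylation (0.075) and, in 1 of 10, cell cycle genes (−0.31). In fibroblasts they were mitochondrially encoded genes in 4 of 19 (down to −0.13), and pro-apoptotic BCL-2 family genes (−0.26) and niche signals (−0.087) in 1.

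Single genes reversed as follows, in log2 ratios. In AT2-like cells, Acta2 was at −0.22 at resolution 0.5, and after thinning Il6 was at −0.083, Ndrg1 at 0.17, Pdgfa at −0.075 and Sdf2l1 at −0.19. Ndrg1 was also at 0.033 without a cell filter, 0.035 at resolution 0.5, 0.045 with each library alone and 0.019 without dissociation stress genes. In transitional-like cells, Bst2 was at 0.011, Cenpf at −0.49 and Hmox1 at 0.60 with each cell called alone, Col6a2 at −0.011 with cells weighted equally, Hspa5 at 0.031 without the single cell and Ndrg1 at −0.027 without its top cell. In fibroblasts after thinning, H2-Ab1 was at −0.14, H2-Eb1 at −0.041 and Ube2c at 0.072.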

Other observations

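The tests of the heat shock genes and the choice of the circadian genes were made after the results were seen. Beyond the pooled fibroblasts and AT2-like cells, the interferon list lay above the middle 95% of random lists in ciliated-like and club-like cells and, among fibroblasts, in alveolar-like, adventitial-like and fibrotic-like cells, but not in peribronchial-like cells (−0.06). In ciliated-like cells its median log2 ratio was 0.48, with 19 of 21 above 0, and Isg15 was 4.03-fold (2.62 to 6.44) higher, with 34 of its 142 navitoclax UMIs in 1 cell. In adventitial-like fibroblasts the median was 0.43, with 22 of 22 above 0, and Ifi27l2a was 1.74-fold (1.62 to 1.85) higher. In club-like cells, where all genes together lay at a median of 0.32, the 6 MHC class II genes had a median of 1.58, and Cd74, the invariant chain of MHC class II, was 3.22-fold (2.97 to 3.49) higher. In those club-like cells the AT2 genes Fabp5 and Scd1 were also 11.4-fold (9.03 to 14.6) and 4.25-fold (3.93 to 4.61) higher, at median depths of 46292 UMIs in the vehicle and 28754 in the navitoclax library, so RNA of AT2-like cells remains open there. In peribronchial-like fibroblasts the ATF6 chaperone list had a median of 0.31, with Hspa5 1.61-fold (1.46 to 1.77) higher.

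Genes of the circadian clock, outside the rule for named genes except Nr1d1, were also compared. Nr1d1 was 2.13-fold (2.0 to 2.27) lower in navitoclax AT2-like cells and 1.45-fold (1.38 to 1.53) lower in fibroblasts. Its paralogue Nr1d2 was 1.18-fold (1.08 to 1.29) lower in AT2-like cells but 1.15-fold (1.04 to 1.27) higher in fibroblasts. In fibroblasts Dbp was 1.49-fold (1.32 to 1.69) and Per1 1.16-fold (1.04 to 1.30) higher, Arntl was 1.38-fold (1.22 to 1.56) lower, and the ratio of Cry1 was 0.955 (0.792 to 1.15). In AT2-like cells Per1 was 1.17-fold (1.05 to 1.30) higher and Cry1 1.42-fold (1.23 to 1.63) lower, and the ratios of Dbp and Arntl were 1.06 (0.881 to 1.26) and 0.972 (0.879 to 1.07). The genes did not all move in the same direction, which by itself does not decide for or against a difference in the phase of the clock. Whether the libraries differed in that phase was not tested. The hour of harvest is not given in the sources used here.

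Hspa1a, the lead gene of the heat shock genes, was higher in navitoclax cells of every compared class, and values were set against 3 technical explanations. A UMI of Hspa1a or Hspa1b, counted together, was seen in 60.2% of thinned navitoclax AT2-like cells and 26.2% of ciliated-like cells, a difference of 34.0 points (29.1 to 38.5), which argues against a few cells whose free RNA reached the others. Fibroblasts held 9.81 and ciliated-like cells 2.42 such UMIs per cell, a quotient of 4.06 (3.81 to 4.33), with 17.2 in AT2-like cells, which argues against free RNA as the whole source in AT2-like cells and fibroblasts and leaves it open in ciliated-like cells. The other dissociation stress genes had a median log2 ratio of −0.12 in fibroblasts, with an upper quartile of 0.10, below the bound of 0.58 set for general dissociation stress, although they were at 0.19 in ciliated-like cells, above all random lists. The interval of Hspa1a lay above 1 in 10 of 10 classes, so a stress response to the drug cannot be told apart from handling or temperature of the whole navitoclax sample, which may act on every cell alike.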
